A study of Mus musculus with 12 samples.

How the data were processed

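The data are 12 arrays of an Affymetrix mouse exon array, 1 array per sample, from primary tumours of 4 related mouse mammary carcinoma lines, 67NR, 168FARN, 4T07 and 4T1, with 3 arrays per line. Per the labels, cells of each line were injected into a mammary fat pad of female BALB/c mice aged 3 months. They give 8 mice injected with 67NR, 11 with 168FARN, 15 with 4T07 and 13 with 4T1. Tumours were taken out when their average size in a group reached 1 to 2 cm. Total RNA was isolated with Trizol, fragmented and biotin-labelled with a whole-transcript terminal labelling kit, per the labels. The design text counts 3 primary tumours per line and the labels number the replicates, but nothing states that each came from its own animal. The p-values here therefore measure the spread between these samples, which may be technical. Each line stands for 1 kind of metastatic behaviour, so line and behaviour cannot be separated.

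The deposited values are log2 signals, 1 per probeset and array. That they are on the log2 scale was read from their range and medians, since no source used here states it. The way the authors summarized, background-corrected and normalized them is not given in the sources used here. The medians of the 12 arrays lay between 7.21 and 7.57, so the arrays were not forced to 1 distribution over these probesets, and the values were used as deposited. All 12 columns were used, and 0 columns were left out. For arrays no read depth exists, and the number of arrays limits the precision.

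Probesets were paired with genes through the probe annotation of the array, and symbols were brought up to date through the RefSeq genes of assembly GRCm38.p6, used for names alone. Of the probesets on the array, 207232 carried 1 symbol, 3882 carried several and 16976 carried none, and probesets without a single symbol were left out of the comparisons. The annotation gave 16207 symbols, of which 14055 were current, 2111 were updated and 41 were kept as given, which left 16185 genes. The pairing was checked by the correlation between probesets of 1 gene across the arrays. In 1741 genes that varied, the median correlation was 0.926, against -0.004 after the probesets were shuffled between genes.

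The level of a gene was the median of the log2 values of its probesets, for the 15025 genes with at least 3 probesets. As a scale of background, the 335 olfactory receptor genes had a median level of 3.12 and a 95th percentile of 5.08, while the median of all genes was 7.39. Groups were compared with limma 3.58.1 in R 4.3.3 with the data.table package, version 1.17.8, by lmFit and eBayes in 1 fit of all 12 arrays with a mean per group and no covariate. The moderated F-test covered the 4 groups, and each of the 6 pairs of groups had its own contrast. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called, with the number that also differed at least 2-fold given beside the count. A gene set a line apart where it was called against each of the other 3 lines, in 1 direction and with a change of at least 1 on the log2 scale. Every adjusted p of a gene below is from limma, levels are means ± SD with n = 3 arrays per line, and SE is the standard error of the limma contrast.

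Exon-level changes were tested with limma's diffSplice, which compares the change of each probeset with the changes of the other probesets of its gene. The test used 110320 probesets in 7349 genes. These were probesets with a mean above the 25th percentile of all probesets, in genes with a mean above the 50th percentile of genes and at least 4 such probesets. A probeset was called at an adjusted p under 0.05 and a relative change of at least 1 on the log2 scale. A splicing index was run as a second test of the same probesets, with the same thresholds. It was the limma test of each probeset's log2 value minus the median, on each array, of its gene's probesets in the exon test. Which exon a probeset covers was not analysed here.

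Fixed gene lists, 24 in number, were tested with camera, which compares a list's change with that of all other genes, at the preset correlation between genes of 0.01, adjusted over all lists and contrasts. Beside it stand the number of members past the gene test, the number adjusted over the list alone, and camera's adjusted p with an estimated correlation. The lists were epithelial junctions and keratins; mesenchymal genes and regulators of epithelial-mesenchymal transition (EMT); collagens and matrix assembly; fibroblast, neutrophil, macrophage and monocyte, T and NK cell, B cell, endothelial, adipocyte, skeletal muscle, mammary secretory and red blood cell markers; extracellular proteases and inhibitors; cell cycle; type I interferon response; antigen presentation; chemokines and cytokines; hypoxia and glycolysis; oxidative phosphorylation; lung metastasis genes of human breast cancer models; TGF-beta targets; splicing regulators; and genes with exons known to be regulated in epithelial or tumour cells. Some genes stand in more than 1 list: 10 of the 23 measured lung metastasis genes and 10 of the 56 measured genes with regulated exons also belong to another list. Whether genes of the last list had exon calls more often than other genes was tested with Fisher's exact test, two-sided, adjusted over the 6 comparisons. The number of probesets per gene was not taken into account.

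The comparisons, tests, thresholds, gene lists, the other settings except the 3 named below as later, and the rule for naming genes were set before the data were examined. Under that rule the main comparisons are 168FARN, 4T07 and 4T1 each against 67NR, and 4T1 against 4T07. In each, the 10 genes with the largest rise and the 10 with the largest fall could be named, among called genes with a standard symbol and at least 3 probesets whose 3 arrays of 1 line all lay above the 3 of the other. The rule adds, for each line set apart, up to 8 higher and 8 lower genes; for each main comparison, the 5 probesets with the largest relative change, at most 1 per gene; and, for each list and comparison, up to 4 members with the largest change past the test. Any member of the epithelial, splicing regulator and regulated-exon lists could also be named. Genes outside the rule are said to have been chosen after their values were seen.

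The steps were tested on simulated data drawn from the real means and spreads. In simulated 168FARN against 67NR, with 15025 genes of which 200 were changed, the gene test recovered 55.0% of genes changed 2-fold and 93.0% of those changed 4-fold, and 5.03% of its calls were unchanged genes. In the exon step of that simulation, with 110350 probesets of which 195 were changed 4-fold relative to their gene, diffSplice recovered 97.9% of them, but 45.0% of its calls were probesets without a change. The splicing index recovered 89.2% with 2.79% such calls, and probesets called by both recovered 88.7% with 1.70%. The exon counts of diffSplice therefore stand beside the number past both tests. All probesets of a changed gene moved alike in the simulation, so it says nothing about probesets that respond less than the rest of their gene.

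Other settings tried were quantile normalization, centring of each array on its median, a fit on the 6 arrays of a pair, the replicate number as a block, an eBayes fit with trend and robust settings, each array left out in turn, gene values as means over probesets, a filter on genes under the 30th percentile of level, gene values from probesets above the 25th percentile, genes with any number of probesets, and gene values without probesets past the exon test. For exons they were no probeset filter, a filter at the 50th percentile, only genes that change by less than 1 on the log2 scale, no minimum relative change and the splicing index. For lists they were an estimated correlation and fry. Those added after seeing the data left out the 2 arrays of 168FARN with high skeletal muscle markers, left out the 2 arrays of 4T07 with high milk gene levels, or required a call by both exon tests. Other groupings of the arrays were counted in 100 draws for the 4 groups and in the 10 possible splits for each pair. Plots were drawn with matplotlib 3.10.9, numpy 2.4.6 and Python 3.11.15.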

Results

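The transcriptomes of 12 primary tumours from 4 mouse mammary carcinoma lines were measured at exon resolution, with 3 arrays for each of 67NR, 168FARN, 4T07 and 4T1. The lines share an origin and are known to differ in how far they spread: 67NR tumours do not metastasize, 168FARN cells reach lymph nodes, 4T07 cells reach the lung without forming visible nodules, and 4T1 cells complete metastasis. Each array gave a log2 signal per probeset, with array medians between 7.21 and 7.57, and 15025 genes were tested. Array numbers in the text are the replicate numbers of the labels, and levels are log2 signals given as mean ± SD with n = 3 arrays per line. A level under 5.08, the 95th percentile of the olfactory receptor genes, is in the range of the background, so a change from or to such a level may be larger than the value given.

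Tumours of 1 line resembled each other closely, and 4T07 and 4T1 tumours resembled each other more than any other pair of lines. The mean correlation of gene levels between arrays of a line lay between 0.980 and 0.988. Between 4T07 and 4T1 it was 0.976, and between the other lines 0.931 to 0.947. Clustering of the 15025 gene levels returned the 4 lines and joined 4T07 with 4T1, apart from 67NR with 168FARN. The first principal component held 43.5% of the variance and the second 23.9%. Of the 15025 genes, 6312 (42.0%) differed among the 4 lines by the F-test. Against 67NR, 3710 genes differed in 168FARN, 3561 in 4T07 and 3356 in 4T1. Against 168FARN, 4248 differed in 4T07 and 4688 in 4T1. Between 4T1 and 4T07, 357 genes differed.

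**Figure D1:**
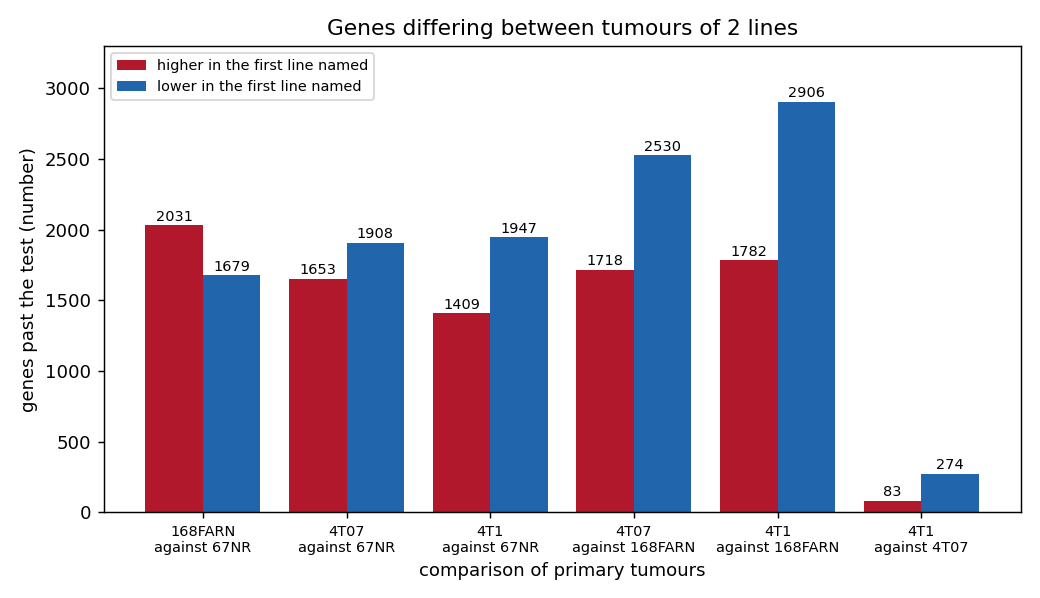
Bars give the number of genes past the test (limma, adjusted p under 0.05, 15025 genes tested, 3 arrays per line) that were higher or lower in the first line named on the horizontal axis. The comparison of 4T1 with 4T07 has the shortest bars, with 83 genes higher and 274 lower in 4T1.

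The comparison of 168FARN with 67NR asks how a tumour whose cells reach lymph nodes differs from one that does not spread. In all, 2031 genes were higher and 1679 lower, and 739 and 499 of them differed at least 2-fold. The genes that rose include Gpnmb, a transmembrane glycoprotein (72.3-fold, to 12.18 ± 0.37), the Wnt modulator Dkk2 (41.0-fold), the thyroid hormone deiodinase Dio2 (34.9-fold) and the methyltransferase Inmt (32.8-fold). Inmt had a wide spread in 67NR (11.51 ± 0.76 in 168FARN against 6.47 ± 1.61). Others rose from levels in the range of the background, so their folds and their order are not measured. They include Dcaf8l (9.37 ± 0.25 against 3.13 ± 0.13), Grem1, a secreted antagonist of bone morphogenetic proteins (10.66 ± 0.53 against 4.55 ± 0.41), Sox2, a transcription factor of stem cells (8.78 ± 0.33 against 3.18 ± 0.38), and the axon guidance gene Sema3d (9.48 ± 0.71 against 4.03 ± 0.24). The genes that fell include Plet1, an epithelial surface protein (-5.23 on the log2 scale, 6.11 ± 0.67 against 11.34 ± 0.17), Cdh2, which encodes N-cadherin (-4.74), Rundc3a (-3.68), the oxygen-sensing prolyl hydroxylase Egln3 (-3.58) and the kinase Mapk13 (-3.35). Rassf6 (3.69 ± 0.31 against 7.99 ± 0.25), the protease Tmprss11f (3.28 ± 0.29 against 7.29 ± 0.21), Ric3, the transporter Slc22a29 and the growth factor Btc (4.74 ± 0.47 against 8.43 ± 0.68) fell to the range of the background.

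Of 15 fibroblast markers measured, 9 rose in 168FARN and the other 6 did not pass the test (9 rose adjusted over the list alone), with a median change of 0.94 and adjusted p = 0.000215 by camera, and adjusted p = 0.313 with an estimated correlation. Their mean level was 9.59 ± 0.05 against 8.26 ± 0.10. Among them were the small leucine-rich proteoglycans Ogn (33.9-fold), Lum (11.80 ± 0.52 against 7.15 ± 0.13) and Dcn (13.55 ± 0.19 against 10.52 ± 0.07), and the fibroblast activation protein Fap (log2 change 2.22). Of 31 genes of collagens and matrix assembly, 16 rose and 5 fell (17 and 5 adjusted over the list alone; camera adjusted p = 0.00604, and adjusted p = 0.677 with an estimated correlation). Thbs2, a thrombospondin, rose from 8.04 ± 0.12 to 12.46 ± 0.31, Col12a1 by 2.27 and the elastin gene Eln by 2.13, while Fbln1 fell by 2.87. The collagen call was lost without 168FARN array 1 (adjusted p = 0.0599). Of 28 extracellular proteases and inhibitors, 8 rose and 6 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.324, and adjusted p = 0.752 with an estimated correlation). The gelatinase Mmp2 rose by 2.70, Adamts1 by 2.20, the cathepsin Ctsk by 2.13 and Mmp11 by 1.85.

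Of 22 interferon-stimulated genes measured, 19 rose in 168FARN and the other 3 did not pass the test (21 rose adjusted over the list alone), with a median change of 0.97, camera adjusted p = 3.18e-09, and adjusted p = 0.371 with an estimated correlation. The nucleic acid sensor Zbp1 rose by 2.18, Ifi44 by 2.04, Rtp4 by 1.65 and the RNA helicase Dhx58 by 1.62. Genes of antigen presentation moved both ways, with 7 of 18 higher and 5 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.717, and adjusted p = 0.96 with an estimated correlation). The immunoproteasome subunits Psmb8 (2.16) and Psmb9 (1.46) rose, and the class II genes Cd74 (-1.56) and H2-Eb1 (-1.25) fell. Of 35 chemokines and cytokines, 5 rose and 9 fell (7 and 10 adjusted over the list alone; camera adjusted p = 0.0914, and adjusted p = 0.58 with an estimated correlation). Among them were the stromal chemokine Cxcl12 (-2.20), the interleukins Il1a (-1.99) and Il33 (1.64), and Ccl6 (-1.58).

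Of 19 endothelial markers, 10 fell in 168FARN and the other 9 did not pass the test (12 fell adjusted over the list alone; median -0.64, camera adjusted p = 8.12e-06, and adjusted p = 0.44 with an estimated correlation). Among them were the VE-cadherin gene Cdh5 (-1.31), Esam (-0.97), Mmrn2 (-0.94) and Pecam1 (-0.91). Of 24 macrophage and monocyte markers, 8 fell and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.000536, and adjusted p = 0.371 with an estimated correlation). The scavenger receptor Cd163 (-1.44), the chemokine receptor Cx3cr1 (-1.36), the mannose receptor Mrc1 (-1.23) and Arg1 (-1.16) fell. Of 24 T and NK cell markers, 7 fell and the other 17 did not pass the test (7 fell adjusted over the list alone; camera adjusted p = 0.000899, and adjusted p = 0.549 with an estimated correlation). They were led by the granzyme gene Gzma (-1.89), Cd8a (-1.68) and Gata3 (-1.32). Of 37 cell cycle genes, 9 fell and 1 rose (16 and 2 adjusted over the list alone; median -0.40, camera adjusted p = 5.81e-06, and adjusted p = 0.58 with an estimated correlation). Kif23 changed by -1.11, Ccnd1 by -0.88 and Aurkb by -0.82, and a rise of 0.93 in Ccne1.

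Skeletal muscle markers differed among the 168FARN arrays, beside all the gene groups named for this line. The mean level of the 15 measured muscle markers was 5.38 on array 1, 7.75 on array 2 and 8.66 on array 3 of 168FARN, against 5.30 to 6.24 on the arrays of the other lines. Of these 15 markers, 5 rose against 67NR and the other 10 did not pass the test (12 rose adjusted over the list alone; median 1.92, camera adjusted p = 0.000664, and adjusted p = 0.632 with an estimated correlation). Among them were the calcium-binding Casq1 (7.33 ± 2.00 against 4.76 ± 0.49, adjusted p = 0.0143), Pvalb (1.98), Tnni2 (1.95) and Tnnc2 (1.92). In a fit with array 1 as the only array of 168FARN, chosen after seeing the data, the median change of the markers turned to -0.237 and the change of Pvalb to -0.249. Of 35 genes of oxidative phosphorylation, 9 rose and the other 26 did not pass the test (9 rose adjusted over the list alone; median 0.27, camera adjusted p = 0.0241, and adjusted p = 0.691 with an estimated correlation). Ndufa4 changed by 1.41 and Ndufa9 by 1.01. The respiratory call was lost without 67NR array 3 (0.0534) or 168FARN array 3 (0.0597). With 168FARN array 1 alone in its group, chosen after seeing the data, 1847 genes differed from 67NR. In that fit 6 fibroblast markers, 14 matrix genes, 5 interferon genes and 3 genes of oxidative phosphorylation rose, and 6 macrophage, 6 T and NK cell and 12 cell cycle genes fell. The list tests then gave adjusted p = 2.22e-05 for interferon genes, 0.00181 for endothelial markers and 0.281 for oxidative phosphorylation, and the lone array was assumed to vary like those of the other lines.

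Most epithelial genes did not pass the test in 168FARN. Of 32 measured, Krt8, Itgb4 and Krt19 rose, Grhl2 and Jup fell (2 rose and 2 fell adjusted over the list alone), and the other 27 did not pass the test (camera adjusted p = 0.265, and adjusted p = 0.891 with an estimated correlation). Krt8, a simple-epithelium keratin, went from 6.60 ± 0.61 to 11.44 ± 0.09 (28.6-fold, adjusted p = 1.31e-07), and the integrin gene Itgb4 rose by 2.48. Cdh2 (-4.74), the adhesion gene Mcam (-1.50), the transcription factor Twist1 (0.99) and S100a4 (-0.92) were among the 3 genes that rose and the 6 that fell of 24 mesenchymal genes and EMT regulators (4 and 6 adjusted over the list alone; camera adjusted p = 0.368, and adjusted p = 0.8 with an estimated correlation). Of 50 splicing regulators, 4 rose and 3 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.373, and adjusted p = 0.891 with an estimated correlation). Mbnl3 (-1.70) and Rbm47 (-1.24) fell, and Rbm38 (0.65) and Ddx17 (0.52) rose.

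The comparison of 4T07 with 67NR sets a line whose cells reach the lung against the line that does not spread. In all, 1653 genes were higher and 1908 lower, and 823 and 609 of them differed at least 2-fold. The genes that rose include the secreted protein gene Wfdc2 (5.32), Tns4 (5.15) and the adhesion gene Amigo2 (5.15). From levels in the range of the background, where folds and their order are not measured, rose Tslp, a cytokine of epithelial cells (10.80 ± 0.55 against 2.99 ± 0.13, adjusted p = 2.65e-09), the hedgehog-binding Hhip (9.35 ± 0.22 against 3.77 ± 0.50), the protease Tmprss11e (9.11 ± 1.47 against 4.17 ± 0.02) and the kinase Rps6ka6 (7.69 ± 0.37 against 2.90 ± 0.16). The genes that fell include Cdh2 (-4.28), the growth factor Ereg (-3.98), the claudin Cldn9 (-3.77) and Cd109 (-3.77). The ectodysplasin receptor Eda2r (4.76 ± 0.30 against 9.53 ± 0.08), Tmem74 (4.11 ± 0.07 against 8.43 ± 0.19), Tmprss11f, the complement receptor Vsig4, Arsj and Ric3 fell to the range of the background.

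Of the 32 epithelial genes, 23 rose in 4T07 and the other 9 did not pass the test (26 rose adjusted over the list alone), with a median change of 1.54, camera adjusted p = 9.43e-16, and adjusted p = 0.371 with an estimated correlation. Krt18 rose 46.3-fold (11.67 ± 0.75 against 6.14 ± 0.90, SE 0.404, adjusted p = 7.09e-07) and its partner Krt8 33.1-fold. The adhesion molecule Epcam rose from 5.73 ± 0.95 to 9.82 ± 1.17, the E-cadherin gene Cdh1 from 6.21 ± 0.16 to 8.64 ± 0.60 (SE 0.254, adjusted p = 1.47e-05), and the protease inhibitor Spint2 by 3.50. The mean level of the list was 7.29, 7.16 and 8.23 on arrays 1, 2 and 3 of 4T07, against 5.79 ± 0.20 in 67NR. The splicing regulator Esrp1, which acts in epithelial cells, rose from 4.53 ± 0.57 to 8.02 ± 1.38 (SE 0.498, adjusted p = 0.000195), Esrp2 by 0.98, Ddx17 by 1.36 and Mbnl2 by 1.20. These belong to the 5 of 50 splicing regulators that rose, while 2 fell (5 rose adjusted over the list alone; camera adjusted p = 0.165, and adjusted p = 0.8 with an estimated correlation). Of 24 mesenchymal genes, 5 rose and 8 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.0618, and adjusted p = 0.632 with an estimated correlation). Besides Cdh2, S100a4 fell from 12.00 ± 0.16 to 8.60 ± 0.26 and the transcription factor Prrx1 by 2.57, while the cadherin Cdh11 rose by 2.55.

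Neutrophil markers were higher in 4T07, with 17 of 18 past the test (17 adjusted over the list alone; median 2.03, camera adjusted p = 1.71e-14, and adjusted p = 0.313 with an estimated correlation). They include Padi4, which modifies histones in neutrophils (4.66), the granule gene Ngp (3.49), the calgranulin S100a9 (3.15) and Lcn2 (3.08), and the mean level of the list was 8.17 ± 0.16 against 6.06 ± 0.27. Of 22 interferon-stimulated genes, 17 rose and the other 5 did not pass the test (20 rose adjusted over the list alone; camera adjusted p = 7.76e-12, and adjusted p = 0.371 with an estimated correlation). Among them were Oasl2 (2.05), Zbp1 (1.82) and the RNA sensor Ifih1 (1.78). Of 18 genes of antigen presentation, 16 rose and the other 2 did not pass the test (16 rose adjusted over the list alone; camera adjusted p = 2.13e-10, and adjusted p = 0.371 with an estimated correlation). Psmb8 changed by 2.41, Psmb9 by 1.82 and the peptide transporter Tap1 by 1.66. Of 35 chemokines and cytokines, 16 rose and 7 fell (16 and 7 adjusted over the list alone; camera adjusted p = 0.0328, and adjusted p = 0.47 with an estimated correlation), a call lost without 67NR array 3 (0.0503) or 4T07 array 1 (0.104). Besides Tslp, Cxcl9 rose by 1.92, and Cxcl12 fell by 2.16 and Il33 by 1.99. Of 12 B cell markers, Jchain (3.17) and Fcrla (0.82) rose (10 rose adjusted over the list alone; camera adjusted p = 0.000427, and adjusted p = 0.514 with an estimated correlation). The immunoglobulin gene Ighg1 rose by 5.30 with a wide spread (11.03 ± 1.66, adjusted p = 0.00113).

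In 4T07, Arg1 rose by 2.49 while Cx3cr1 (-1.89), Mrc1 (-1.50) and Csf1r (-0.84) fell, the 1 rise and 3 of the 4 falls among 24 macrophage and monocyte markers (1 and 4 adjusted over the list alone; camera adjusted p = 0.306, and adjusted p = 0.791 with an estimated correlation). Of 24 T and NK cell markers, 6 rose and 2 fell (8 and 2 adjusted over the list alone), with Cd3g at 1.19, Ctla4 at 1.06, Gzma at -2.20 and Ncr1 at -1.20; camera gave adjusted p = 0.0434, and adjusted p = 0.691 with an estimated correlation. This call was lost after quantile normalization (0.0676) and without 67NR array 2 (0.0744) or 3 (0.0594), 168FARN array 2 (0.0515) or 4T07 array 2 (0.407). Of 19 endothelial markers, 5 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0328, and adjusted p = 0.691 with an estimated correlation). Cdh5 changed by -0.87 and Kdr by -0.68. The endothelial call was lost without 67NR array 1 (0.102), 4T07 array 1 (0.0749) or 4T07 array 2 (0.105). Of 5 red blood cell markers, Alas2 fell by 1.04 and the other 4 did not pass the test (1 fell adjusted over the list alone; camera adjusted p = 0.347, and adjusted p = 0.632 with an estimated correlation).

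Genes of hypoxia and glycolysis rose in 4T07, 18 of 31 with 1 fall (20 and 2 adjusted over the list alone; median 0.69, camera adjusted p = 5.87e-09, and adjusted p = 0.371 with an estimated correlation). The enolase Eno2 rose by 3.31, the carbonic anhydrases Car9 by 3.31 and Car12 by 3.05, and the aldolase Aldoc by 3.15. Of 22 TGF-beta targets, 10 rose and the other 12 did not pass the test (11 rose adjusted over the list alone; camera adjusted p = 7.16e-06, and adjusted p = 0.313 with an estimated correlation). The matricellular gene Ccn2 changed by 3.20, Il11 by 1.67 and Ltbp2 by 1.33. Matrix genes rose too, 18 of 31 with 2 falls (18 and 2 adjusted over the list alone; camera adjusted p = 7.16e-06, and adjusted p = 0.47 with an estimated correlation). Among them were Col12a1 (3.20), Thbs2 (2.49) and the tenascin Tnc (1.95), with a fall of 2.23 in Fbln1. Of 28 proteases and inhibitors, 11 rose and 1 fell (13 and 2 adjusted over the list alone; camera adjusted p = 4.4e-05, and adjusted p = 0.371 with an estimated correlation). Serpine2 changed by 4.52, Mmp13 by 2.57, Mmp12 by 2.55 and Mmp8 by 2.43. Of 23 genes linked to lung metastasis in human breast cancer models, 9 rose and 1, Ereg, fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00494, and adjusted p = 0.371 with an estimated correlation). Of 15 fibroblast markers, 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0293, and adjusted p = 0.371 with an estimated correlation), a call lost without 4T07 array 1 (0.078). Of 37 cell cycle genes, 22 fell and the other 15 did not pass the test (27 fell adjusted over the list alone; median -0.58, camera adjusted p = 8.07e-07, and adjusted p = 0.555 with an estimated correlation). The kinases Aurkb and Cdk2 changed by -0.89 and -0.87, and the replication factor Cdc6 by -0.88. Of 35 genes of oxidative phosphorylation, 5 fell and the other 30 did not pass the test (3 fell adjusted over the list alone; camera adjusted p = 0.0973, and adjusted p = 0.775 with an estimated correlation).

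Milk genes differed among the 4T07 arrays, beside all the groups named for this line. The mean level of 11 mammary secretory markers was 5.97, 7.21 and 7.48 on arrays 1, 2 and 3 of 4T07. Of these markers 6 rose against 67NR and the other 5 did not pass the test (7 rose adjusted over the list alone; median 1.20, camera adjusted p = 0.000315, and adjusted p = 0.371 with an estimated correlation), a call lost without genes under the 30th percentile of level (0.104). They include the casein genes Csn1s2a (3.96, 7.31 ± 1.80), Csn1s1 (3.69, 6.54 ± 2.25) and Csn2 (3.10), and Ltf (1.99), which is also a neutrophil marker. With 4T07 array 1 alone in its group, chosen after seeing the data and assumed to vary like the other lines, 2920 genes differed from 67NR. The mean list levels on array 1 were 7.29 for epithelial, 7.99 for neutrophil, 8.74 for interferon, 10.57 for antigen presentation, 9.93 for hypoxia and 8.98 for cell cycle genes. In 67NR they were 5.79, 6.06, 7.80, 9.78, 9.01 and 9.70. Array 1 of 4T07 also had the lowest median signal of the 12 arrays, 7.21, against 7.34 to 7.44 in 67NR. A shift of that whole array and an effect of leaving out the milk-high arrays therefore cannot be told apart.

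The comparison of 4T1 with 67NR sets the line that completes metastasis against the line that does not spread. In all, 1409 genes were higher and 1947 lower, and 689 and 690 of them differed at least 2-fold. The genes that rose include Krt18 (77.0-fold), the imprinted non-coding RNA gene H19 (76.9-fold), Krt8 (44.4-fold), Wfdc2 (5.21 on the log2 scale), Gpa33 (4.89), the matrix gene Npnt (4.85), the monooxygenase-like Moxd1 (4.76) and Padi4 (4.65). Tmprss11e (10.98 ± 0.19 against 4.17 ± 0.02) and Hhip (10.11 ± 0.19 against 3.77 ± 0.50) rose from levels in the range of the background, so their folds and their rank are not measured. The genes that fell include the protocadherin Pcdh7 (-4.62), Cdh2 (-4.42), the phosphatase Acpp (-4.32) and Ereg (-4.06). Eda2r (4.37 ± 0.39 against 9.53 ± 0.08), Xlr (3.47 ± 0.62 against 8.06 ± 0.23), Hdgfl3 (3.80 ± 0.28 against 8.34 ± 0.07), Tmprss11f, 1700049E17Rik1 and Ric3 fell to the range of the background.

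Of the 32 epithelial genes, 25 rose in 4T1 and the other 7 did not pass the test (25 rose adjusted over the list alone), with a median change of 1.90, camera adjusted p = 3.84e-19, and adjusted p = 0.323 with an estimated correlation. Krt18 reached 12.40 ± 0.24 (adjusted p = 2.28e-07), Epcam 10.36 ± 0.28 and Cdh1 8.82 ± 0.30 (adjusted p = 7.36e-06), and Itgb4 rose by 3.97, Spint2 by 3.84 and the desmosomal cadherin Dsg2 by 3.13. The mean level of the list was 7.88 ± 0.13 against 5.79 ± 0.20 in 67NR. Esrp1 rose by 3.32 to 7.85 ± 0.22 (adjusted p = 0.000302), Esrp2 by 1.57, Mbnl2 by 1.25 and Rbm47 by 0.94, among 7 of 50 splicing regulators that rose and 4 that fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.174, and adjusted p = 0.8 with an estimated correlation). Of 24 mesenchymal genes, 4 rose and 6 fell (7 and 8 adjusted over the list alone; camera adjusted p = 0.395, and adjusted p = 0.811 with an estimated correlation). S100a4 changed by -2.42, Prrx1 by -2.32 and the transcription factor Snai2 by -2.29.

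**Figure D2:**
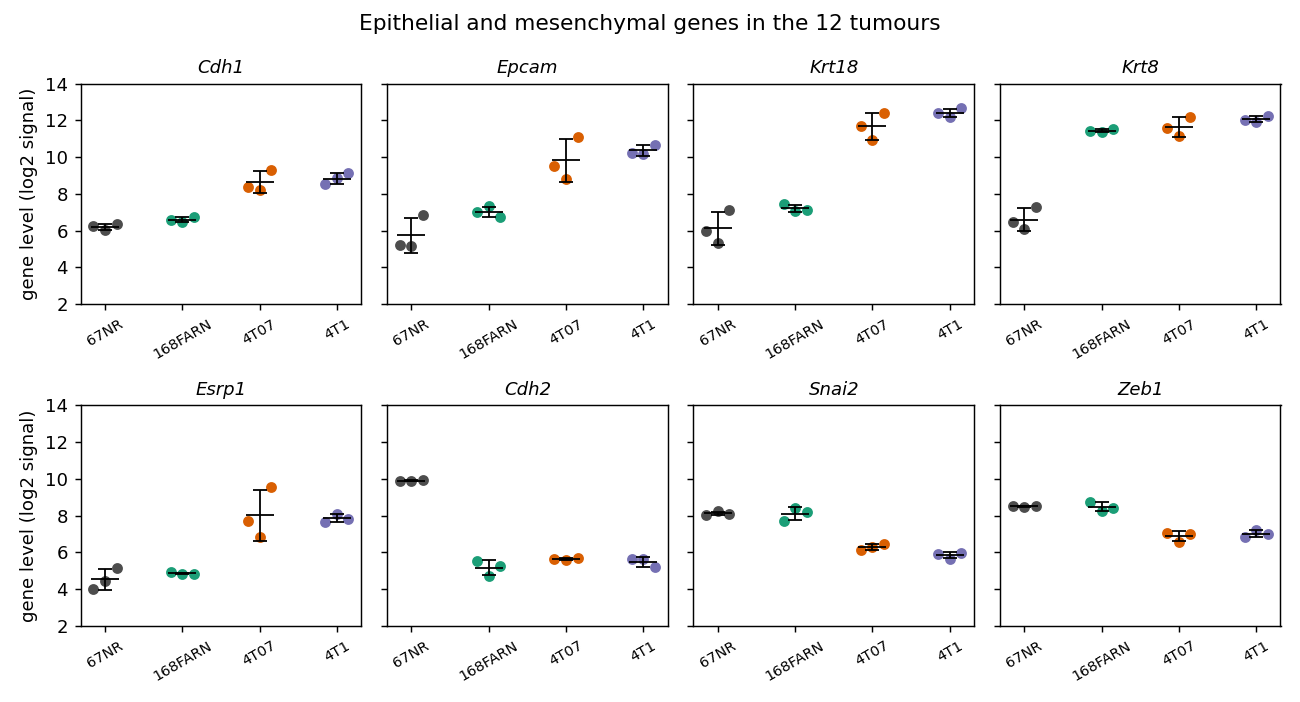
Points give the log2 level of Cdh1, Epcam, Krt18, Krt8, Esrp1, Cdh2, Snai2 and Zeb1 on each of the 12 arrays by line, with the mean as a horizontal mark and the SD as error bars (n = 3). Zeb1 was chosen after its values were seen, and Krt18 averaged 12.40 in 4T1 and 11.67 in 4T07 against 6.14 in 67NR.

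Neutrophil markers rose in 4T1, 11 of 18 with the other 7 not past the test (13 rose adjusted over the list alone; median 1.43, camera adjusted p = 8.8e-09, and adjusted p = 0.313 with an estimated correlation). Lcn2 went from 8.55 ± 0.54 to 12.45 ± 0.38, S100a9 rose by 2.20 and Trem1 by 2.06. Hypoxia and glycolysis genes rose, 16 of 31 with the other 15 not past the test (18 rose and 1 fell adjusted over the list alone; median 0.70, camera adjusted p = 8.8e-09, and adjusted p = 0.371 with an estimated correlation). Car9 changed by 3.54, Car12 by 3.48, Aldoc by 3.14 and the lactate transporter Slc16a3 by 2.15. Of 31 matrix genes, 19 rose and 2 fell (21 and 2 adjusted over the list alone; camera adjusted p = 9.47e-08, and adjusted p = 0.391 with an estimated correlation). Among them were Col12a1 (3.45), Thbs2 (2.94) and the periostin gene Postn (2.06). TGF-beta targets rose, 11 of 22 with the other 11 not past the test (13 rose adjusted over the list alone; camera adjusted p = 8.76e-06, and adjusted p = 0.313 with an estimated correlation). Ccn2 changed by 1.59, Col7a1 by 1.50 and Skil by 1.31. Of 28 proteases and inhibitors, 8 rose and 3 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.44 with an estimated correlation). They were led by Serpine2 (4.27), Mmp12 (2.35) and Mmp13 (2.24). Of 37 cell cycle genes, 24 fell and the other 13 did not pass the test (32 fell adjusted over the list alone; median -0.59, camera adjusted p = 4.44e-09, and adjusted p = 0.469 with an estimated correlation). Among them were Cdk1 (-1.08), Ttk (-0.99) and the proliferation marker Mki67 (-0.93).

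Interferon genes rose in 4T1, 11 of 22 with 1 fall, Ifit2 (13 and 2 adjusted over the list alone; camera adjusted p = 0.000134, and adjusted p = 0.58 with an estimated correlation). In the antigen presentation list 7 of 18 genes rose, while the other 11 did not pass the test (7 rose adjusted over the list alone; camera adjusted p = 1.54e-05, and adjusted p = 0.44 with an estimated correlation). Psmb8 changed by 2.03 and Psmb10 by 1.82. Chemokines and cytokines went both ways, 9 higher and 7 lower of 35 (11 and 7 adjusted over the list alone; camera adjusted p = 0.226, and adjusted p = 0.691 with an estimated correlation). Tslp rose by 4.57 and Csf3, the growth factor of neutrophils, by 2.09, while Cxcl12 fell by 2.39 and Il33 by 2.33. Arg1 rose by 2.66 among 24 macrophage markers of which 3 rose and 4 fell (3 and 4 adjusted over the list alone), a list whose median (-0.01) and mean (0.04) differ in sign, with camera upward at adjusted p = 0.889 and adjusted p = 0.988 with an estimated correlation. Of 24 T and NK cell markers, 5 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.52, and adjusted p = 0.93 with an estimated correlation). Gzma changed by -2.51, Klrd1 by -1.58 and Nkg7 by -1.24. Of 19 endothelial markers, 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.174, and adjusted p = 0.8 with an estimated correlation). Among 15 fibroblast markers, 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.57, and adjusted p = 0.8 with an estimated correlation). Of 16 adipocyte markers, Fabp4 (-1.70) and Pnpla2 (-0.74) fell (2 adjusted over the list alone; camera adjusted p = 0.135, and adjusted p = 0.791 with an estimated correlation). The mean adipocyte level was highest on 67NR array 3 (7.69, against 6.73 and 6.86 on arrays 1 and 2). Of 23 lung metastasis genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0642, and adjusted p = 0.574 with an estimated correlation). Tnc changed by 2.05, Vcam1 by 1.36 and Ereg by -4.06.

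**Figure D3:**
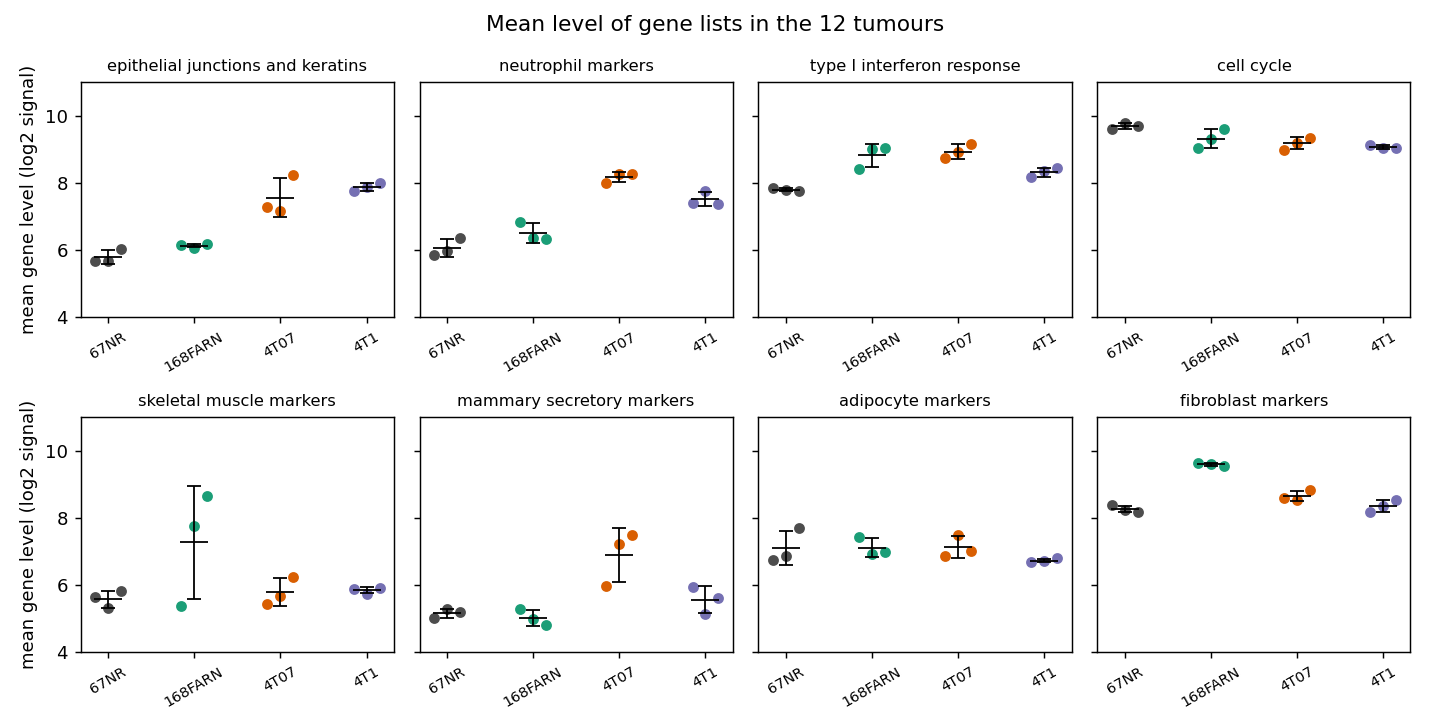
Points give the mean log2 level over the genes of 8 fixed lists on each of the 12 arrays by line, with the group mean as a horizontal mark and the SD as error bars (n = 3). Epithelial genes averaged 7.56 in 4T07 and 7.88 in 4T1 against 5.79 in 67NR, and muscle markers stood at 7.75 and 8.66 on 168FARN arrays 2 and 3.

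The comparison of 4T1 with 4T07 asks what distinguishes full metastasis from spread without visible nodules. Far fewer genes passed the test here. In all, 83 genes were higher and 274 lower in 4T1, and 39 and 190 of them differed at least 2-fold. The share of higher calls was 23.2% as deposited, 35.1% of 481 after quantile normalization and 39.0% of 433 after centring on array medians. The median signal of 4T07 array 1 was the lowest of all arrays, 7.21, so a share taken with that array alone also carries this difference. The count of called genes fell to 158 without 4T07 array 2 and to 156, 233 and 224 without 4T1 array 1, 2 and 3. It rose to 531 without 4T07 array 3. Without the 2 milk-high 4T07 arrays, chosen after seeing the data, it was 147, of which 53.7% were higher.

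Nptx1, a neuronal pentraxin, rose 11.4-fold (9.84 ± 0.20 against 6.33 ± 0.23, adjusted p = 4.18e-05), Bmp7, a bone morphogenetic protein, by 2.61, Fcrls by 2.38, H19 by 2.00, the proton channel gene Otop1 by 1.93, the EMT transcription factor Twist1 by 1.68 (8.99 ± 0.30 against 7.31 ± 0.52, adjusted p = 0.00258), the urate oxidase Uox by 1.62, the glypican Gpc4 by 1.52 and Nectin3 by 1.45. The genes that fell include Inmt (-3.61), Medag (-3.38), the endothelial proteoglycan Esm1 (-3.33), Tslp (-3.24), Angptl7 (-3.11) and the galectin Lgals7 (-2.94). Xlr (3.47 ± 0.62 against 7.06 ± 0.47), Hdgfl3 (3.80 ± 0.28 against 6.96 ± 0.54) and the caseins Csn1s2a (3.78 ± 0.93 against 7.31 ± 1.80) and Csn2 (4.93 ± 1.05 against 8.31 ± 1.20) fell to the range of the background. Of 24 mesenchymal genes, Twist1 and S100a4 (0.98) rose (both also adjusted over the list alone; camera adjusted p = 0.0261, and adjusted p = 0.58 with an estimated correlation), a call lost without 4T07 array 2 (0.247), without 4T1 array 2 (0.0632) and after quantile normalization (0.0659). Of 32 epithelial genes, 0 passed limma's test over all genes, 5 were higher and 1 lower at an unadjusted p under 0.05, and 1 was higher adjusted over the list alone. Their median change was 0.39 (camera adjusted p = 0.000437, and adjusted p = 0.632 with an estimated correlation; fry adjusted p = 0.339). The epithelial call was lost without 4T07 array 2 (0.172).

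Of 22 interferon-stimulated genes, 5 fell in 4T1 against 4T07 and the other 17 did not pass the test (14 fell adjusted over the list alone; median -0.63, camera adjusted p = 7.67e-13, and adjusted p = 0.371 with an estimated correlation). Zbp1 changed by -1.17, the antiviral Rsad2 by -0.97 and Oas2 by -0.86. Of 18 genes of antigen presentation, Tap1 (-0.96) and H2-Q7 (-0.73) fell (5 adjusted over the list alone; camera adjusted p = 4.57e-07, and adjusted p = 0.371 with an estimated correlation). Of 18 neutrophil markers, Ngp (-1.60) and Mpo (-1.08) fell (11 adjusted over the list alone; median -0.72, camera adjusted p = 5.34e-07, and adjusted p = 0.323 with an estimated correlation). Of 24 T and NK cell markers, Klrd1 (-1.55), Nkg7 (-1.44) and Gzmk (-1.18) fell (7 adjusted over the list alone; camera adjusted p = 9.52e-06, and adjusted p = 0.391 with an estimated correlation). Jchain fell by 2.18 among 12 B cell markers (2 adjusted over the list alone; camera adjusted p = 0.0472, and adjusted p = 0.691 with an estimated correlation). This call was lost without 67NR array 3 (0.0529), 168FARN array 2 (0.0579) or 3 (0.0556), or 4T07 array 1 (0.254) or 2 (0.396), and turned upward without 4T1 array 2 (0.505). The B cell level was 7.06, 5.38 and 7.12 on arrays 1, 2 and 3 of 4T1. Of 11 mammary secretory markers, Csn1s2a, Csn2 and Csn3 (-2.59) fell (7 fell and 1 rose adjusted over the list alone; median -0.95, camera adjusted p = 6.15e-05, and adjusted p = 0.371 with an estimated correlation). The milk gene call was lost without genes under the 30th percentile of level (0.992), and their level was 5.94, 5.13 and 5.60 on the 4T1 arrays. Without the 2 milk-high 4T07 arrays, array 1 alone is left, which gives no spread for 4T07. Its mean level was 8.74 for interferon genes, 7.99 for neutrophil markers and 5.97 for milk genes. The 4T1 levels were 8.32 ± 0.14, 7.52 ± 0.20 and 5.56 ± 0.41. Of 24 macrophage markers, Cx3cr1 (1.20) and Mrc1 (0.84) rose and the monocyte gene Ly6c2 (-1.22) fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.00601, and adjusted p = 0.478 with an estimated correlation). Of 15 fibroblast markers, Ogn (-1.88), Dcn (-1.11), Pdgfra (-0.87) and C3 (-0.85) fell (5 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.371 with an estimated correlation), a call lost without 4T07 array 1 (0.104), 4T07 array 3 (0.0675) or 4T1 array 1 (0.0763). Of 35 chemokines and cytokines, Tslp, Cxcl5 (-2.36), Il11 (-2.02) and Ccl8 (-1.70) fell and the other 31 did not pass the test (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0463, and adjusted p = 0.514 with an estimated correlation). This call was lost after quantile normalization (0.0577) and without 67NR array 3 (0.0518), any of the 168FARN arrays (0.0615, 0.0505 and 0.0531), 4T07 array 1 (0.212) or 4T1 array 1 (0.0763) or 3 (0.159). Of 22 TGF-beta targets, 2 fell and the other 20 did not pass the test, with a median of 0.07 and a mean of -0.10 (3 fell adjusted over the list alone; camera upward at adjusted p = 0.962, and adjusted p = 0.992 with an estimated correlation).

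Against 168FARN, 1718 genes were higher and 2530 lower in 4T07, and 1782 were higher and 2906 lower in 4T1. Of 32 epithelial genes, 21 rose in 4T07 and 22 in 4T1, and the others did not pass the test (23 and 22 adjusted over the list alone; camera adjusted p = 5.39e-13 and 1.71e-14, and adjusted p = 0.371 for each with an estimated correlation). Krt18 rose by 4.46 and 5.19, Spint2 by 3.43 and 3.77, and Esrp1 by 3.17 and 3.00. Of 31 hypoxia and glycolysis genes, 15 and 17 rose and 1 fell in each (16 and 18 rose and 1 fell in each adjusted over the list alone; camera adjusted p = 4.44e-09 and 6.06e-08, and adjusted p = 0.371 for each with an estimated correlation). Egln3 changed by 4.80 in 4T07 and 4.63 in 4T1, and Aldoc by 2.93 and 2.92. Of 15 fibroblast markers, 4 rose and 9 fell in 4T07, and 3 rose and 10 fell in 4T1 (the same numbers adjusted over the list alone; camera adjusted p = 0.0636 and 0.012, and adjusted p = 0.469 and 0.371 with an estimated correlation). Ogn (-4.75 and -6.63), Lum (-3.70 and -3.18) and Cd34 (-3.25 and -3.07) fell, Tslp rose from 3.18 ± 0.42 to 10.80 ± 0.55 and 7.56 ± 0.12, and Arg1 by 3.65 and 3.82. Of 35 genes of oxidative phosphorylation, 17 fell in 4T07 and 14 in 4T1 (17 and 14 adjusted over the list alone; camera adjusted p = 0.000215 and 0.0102, and adjusted p = 0.549 and 0.677 with an estimated correlation). Of 15 muscle markers, high on 168FARN arrays 2 and 3, 3 fell in 4T07 and 4 in 4T1 (7 and 0 adjusted over the list alone; camera adjusted p = 0.00928 and 0.0168, and adjusted p = 0.691 and 0.709 with an estimated correlation). Without those 2 arrays the median change of the markers turned upward, to 0.284 in 4T07 and 0.314 in 4T1. With 168FARN array 1 alone, chosen after seeing the data, 2112 genes differed in 4T07 and 2470 in 4T1, and the respiratory call was lost in 4T1 (0.111).

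Many genes set 1 line apart from each of the other 3 at 2-fold or more. For 168FARN there were 421 (290 higher and 131 lower), for 67NR 329 (181 and 148), for 4T07 76 (65 and 11) and for 4T1 54 (12 and 42). In 67NR, Cdh2, Tmprss11f, Ric3, Rundc3a and Btc were higher than in each other line, and Krt8 was lower by at least 28.6-fold, with the bone sialoprotein gene Ibsp, Scara3, Amigo2, Clu and Grem1 also lower. In 168FARN, Dcaf8l, Sox2, Dkk2, Ogn, Dppa4, the growth factor Igf2 (11.64 ± 1.07) and Sema3d were higher, and Plet1, Slc22a29, Egln3, Rassf6 and the phosphatase Dusp4 were lower. In 4T07, Csn1s2a, Tslp (at least 9.46-fold), Csn2, Esm1 and the immunoglobulin genes Iglv1 and Ighg2b were higher, and Fcrls, Twist1, Gpc4 and Nectin3 were lower. In 4T1, Bmp7 (at least 6.11-fold), H19 (at least 4.01-fold), the vitamin D hydroxylase Cyp24a1 and Hoxa5 were higher, and Xlr, Hdgfl3, Medag and Pcdh7 were lower. The 4T07 count was 42 without 4T07 array 2 and 47 without 4T1 array 1, and the 4T1 count was 31 without 4T07 array 2, 102 without 4T07 array 3 and 32 without 4T1 array 1.

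At the level of exons, the comparison asks which parts of a gene change otherwise than the rest of it, the subject that the series names. The clearest case was Fgfr2, the gene of a growth factor receptor with mutually exclusive exons used in epithelial and mesenchymal cells. The gene rose by 2.09 in 4T07 and 2.28 in 4T1 against 67NR (9.85 ± 0.19 and 10.04 ± 0.09 against 7.76 ± 0.18, SE 0.219, adjusted p = 1.51e-05 and 6.78e-06), while a pair of its probesets fell. The signal of probeset 5177161 was 4.21 ± 0.49 in 4T07 and 2.79 ± 0.26 in 4T1 against 7.49 ± 0.33 in 67NR, and that of probeset 5179865 was 3.97 ± 0.43 and 3.83 ± 0.09 against 7.55 ± 0.34. Relative to the other probesets, 5179865 fell by 5.18 in 4T07 (adjusted p = 1.71e-40 by diffSplice and 1.27e-06 by the splicing index) and 5177161 by 6.36 in 4T1 (1.32e-52 and 5.86e-07). Another pair, 5026159 and 5355690, went the other way, from 5.89 ± 0.76 and 6.62 ± 0.27 in 67NR to 10.62 ± 0.15 and 10.06 ± 0.21 in 4T07 and 10.59 ± 0.07 and 10.11 ± 0.12 in 4T1. Against 168FARN, 5179865 differed by -4.50 in 4T07 and -4.65 in 4T1, and the gene rose by 1.40 and 1.59.

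**Figure D4:**
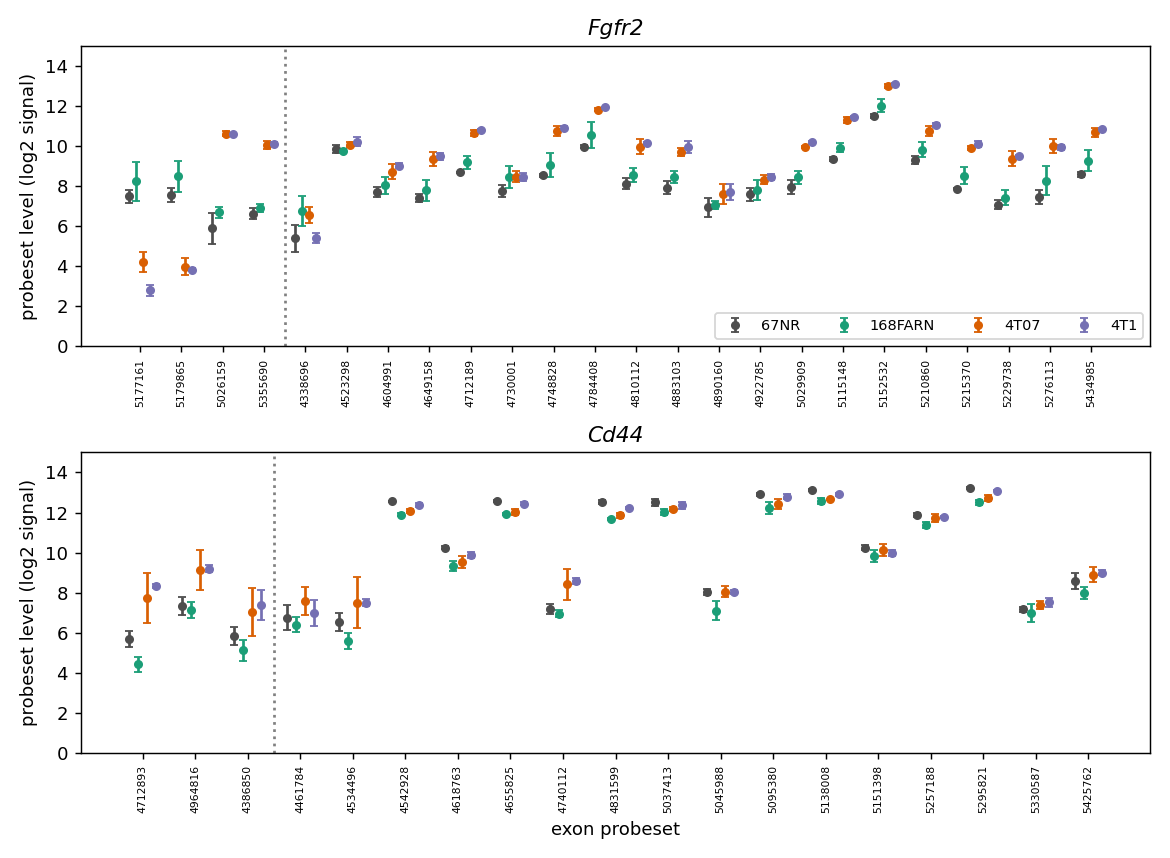
Points give the mean log2 signal of each Fgfr2 and Cd44 probeset by line, bars the SD (n = 3), and the probesets to the left of the dotted line are those with the largest relative change past the test in 4T1 against 67NR, up to 4 per gene. In Fgfr2, probesets 5177161 and 5179865 stand lower in 4T07 and 4T1 than in 67NR, and 5026159 and 5355690 stand higher.

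Cd44, an adhesion receptor with variable exons, gained signal in particular probesets while the gene moved by 0.01 in 4T07 and 0.15 in 4T1. That gene level is a median over probesets that moved both ways. Bright probesets such as 4831599 fell in 4T07 (11.81, 12.00 and 11.78 on its arrays against 12.38, 12.58 and 12.55 in 67NR). Relative to the gene, probeset 4712893 rose by 1.93 in 4T07 and 2.39 in 4T1, and probeset 4964816 by 1.65 and 1.54, past both exon tests. In 168FARN, probeset 5201971 of the fibronectin gene Fn1 rose by 1.57 relative to its gene (12.13 ± 0.55 against 10.17 ± 0.09), and 3 probesets of Enah, which remodels actin, fell relative to a gene that rose by 1.56 (4913370 by 1.71, splicing index adjusted p = 0.0315). In Fgfr1, which fell by 2.20 in 4T07 and 2.02 in 4T1, probeset 5333109 had a signal of 10.10 ± 0.37 and 10.18 ± 0.25, against 10.04 ± 0.14 in 67NR. Few probesets past both exon tests had an own signal that moved by 2-fold or more, past the test, against that of the gene. Against 67NR they lay in Mtus1 and Polr3f in 168FARN, in Ampd3, Cyp39a1, Etl4, Fgfr2 and Pde4d in 4T07, and in Ampd3, Fgfr2 and Rgs3 in 4T1. Except Fgfr2, these genes were chosen after their values were seen.

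Against 67NR, diffSplice called 820 probesets in 508 genes in 168FARN, 741 in 396 genes in 4T07 and 812 in 438 genes in 4T1, and 298, 401 and 414 of these also passed the splicing index. Against 168FARN it called 840 in 4T07 and 1388 in 4T1, with 347 and 622 past both. Between 4T1 and 4T07 it called 164, of which 8 passed both, and 439 without 4T07 array 1. On simulated data 45.0% of diffSplice calls were probesets without a change, against 1.70% of those past both tests. The simulation held no probesets that respond less than the rest of their gene. It therefore cannot tell how many calls past both tests are of that kind. Clustering of the 110320 probesets relative to their genes placed 168FARN array 3 with 4T07 array 3, and the other 4T07 arrays with 4T1. For the 87892 probesets in genes that changed by less than 1 on the log2 scale among the lines, the clusters did not follow the lines. Among all 4 lines, 751 of 7349 genes (10.2%) had an exon-level difference. The relative change of most called probesets was opposite in sign to the change of their gene, 63.8%, 68.8% and 68.1% in 168FARN, 4T07 and 4T1 against 67NR. Among probesets past both tests these shares were 71.8%, 76.6% and 72.7%, so requiring both tests did not lower the share of such opposite changes. The largest relative changes were often of this kind: Grem1 probeset 4781973 was at 8.18 ± 0.38 in 168FARN and 8.23 ± 0.38 in 67NR while its gene rose, and Moxd1 probeset 4432992 was at 9.57 ± 0.21 in 4T07 and 9.50 ± 0.14 in 67NR. Scara3, Igf2 and Clu in 168FARN (-4.26, -4.05 and -3.86 relative to the gene), Padi4 (-4.14) and Epcam (-3.67) in 4T07, and Serinc2 (-4.11) and Nptx1 (-4.07) in 4T1 had relative falls in genes that rose. Plet1 in 168FARN had a relative rise (4.91) in a gene that fell, with a difference of -0.63 in its own signal, and Coro6 in 4T07 had a relative rise (3.62) in a gene that rose by 2.04. Between 4T1 and 4T07 the largest were in Nptx1 (-3.48), Zdhhc6 (-2.55), Twist1 (-2.27), Mmp28 (2.23) and Cidec (-2.21), of which Mmp28 alone passed the splicing index (adjusted p = 0.0443, against 0.0968, 0.648, 0.0968 and 0.635 for the others).

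Genes with exons known to be regulated in epithelial or tumour cells had exon calls more often than other genes in some comparisons. Of the 48 tested, 8 had a diffSplice call in 4T1 against 67NR (16.7% against 5.89% of 7301 other genes, Fisher's exact adjusted p = 0.0206) and 13 in 4T1 against 168FARN (27.1% against 11.8%, adjusted p = 0.0186). The adjusted p was 0.572 for 168FARN against 67NR, 0.394 for 4T07 against 67NR, 0.0912 for 4T07 against 168FARN and 0.0977 for 4T1 against 4T07. Counting probesets past both tests, 6 of the 48 had a call in 4T07 against 168FARN (adjusted p = 0.00507) and 10 in 4T1 against 168FARN (adjusted p = 0.000484), and the call of 4T1 against 67NR was lost, with 4 genes (adjusted p = 0.0681). At gene level, 9 of 56 rose and 9 fell in 4T1 against 67NR (11 and 10 adjusted over the list alone), with a median of -0.06, a mean of 0.07 and camera upward at adjusted p = 0.875, and adjusted p = 0.992 with an estimated correlation. In 168FARN, 8 rose and 15 fell (9 and 16 adjusted over the list alone; camera adjusted p = 0.0375, and adjusted p = 0.7 with an estimated correlation), a call lost without 168FARN array 2 (0.178).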

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

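Except for the counts of other splits of the arrays, the tests in this part were chosen only after the results were seen, and the genes Acta1, Ckm and Cfd were chosen after their values were seen. A signal appeared in data that the comparisons left out, the 20858 probesets without a single gene symbol. Against 67NR, 646 of these were higher and 601 lower in 168FARN, 866 higher and 621 lower in 4T07, and 549 higher and 805 lower in 4T1 (limma, adjusted p under 0.05). What they measure was not analysed here.

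Many exon calls were relative changes opposite in sign to the change of the gene, without the probeset's own signal having to move. Each called gene was counted once per comparison against 67NR, by its called probeset with the largest relative change. In genes that changed at least 2-fold, this change was opposite to the gene in 86.9% (618 of 711, 95% exact interval 84.2% to 89.3%). A gene can count in more than 1 comparison, and the comparisons share the 67NR arrays, so the interval is too narrow. Probesets that respond less than the rest of their gene would do so, and a weaker response may account for many of these calls. In genes that changed less than 2-fold the share was 58.3% (368 of 631, interval 54.4% to 62.2%, too narrow for the same reason). It lies between an even share and that of the first genes, so weak probesets and a change of exon use cannot be told apart. For Fgfr2 the pair of probesets was picked because their own signal fell in 4T07 and 4T1, so the direction restates the choice. The smallest fall was -3.27 (upper limit -2.48, which does not allow for the choice) while the gene rose. A fall of that size argues against weak probesets for this pair, which leaves a change in exon use as a hypothesis. Among genes that changed less than 2-fold, those with known regulated exons had calls more often in 4T1 against 67NR (odds ratio 4.56, Fisher's exact adjusted p = 0.0433 over 6 comparisons, 5 of 43 against 187 of 6674). That test did not take the number of probesets per gene into account, and a gene with more probesets has more chances of a call. It therefore cannot decide between weak probesets and a change of exon use. The odds ratio was 1.11 in 168FARN (adjusted p = 0.843) and 0.998 in 4T07 against 67NR (1 of 43 genes, adjusted p = 1), 1.87 in 4T07 against 168FARN (0.348) and 4.13 in 4T1 against 4T07 (0.0846), so the difference was past the threshold in 4T1 against 67NR alone. Probesets past both tests were compared only over all 48 tested genes of that list, whatever the change of the gene, and there 4T1 against 67NR was not past the threshold (adjusted p = 0.0681). In 4T1 against 168FARN the odds ratio was 2.61 (0.965 to 6.08, adjusted p = 0.0846), too few genes to decide, and between 4T1 and 4T07 simulated arrays without an exon change gave 111 calls against the 164 observed, so unequal noise between probesets may account for most of them.

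Skeletal muscle markers stood high on arrays 2 and 3 of 168FARN. Of 15 markers, 14 (93.3%) were higher on both arrays than on each of the other 10, with Acta1 at 9.30 ± 2.21 and Ckm at 9.21 ± 2.35 in 168FARN. The arrays were picked by the mean of the same markers, so this count restates it. That mean was 5.38 on array 1 of 168FARN, against 7.75 and 8.66 on arrays 2 and 3. The rise was therefore not shared by all 3 arrays of the line. Muscle tissue in those samples and a difference of the 168FARN line that varies between its samples cannot be told apart. None of the markers stands in another list, and 10 of the 15 lay above the background range in 67NR. With array 1 alone, the median change of oxidative phosphorylation genes was 0.0303 (-0.253 to 0.313) against 0.267 with all arrays, so whether muscle or the tumour cells raised those genes cannot be told apart, since 1 array is too few.

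Of 32 epithelial genes, 23 rose in 4T07 and 25 in 4T1 against 67NR (camera adjusted p = 0.371 and 0.323 with an estimated correlation), and normal mammary fat pad in those samples would raise adipocyte markers with them. The change of the epithelial minus the adipocyte mean level was 1.73 in 4T07 and 2.46 in 4T1 (SE 0.361), against 1.77 and 2.09 for the epithelial genes alone, so the fat markers did not rise with them. This cannot exclude fat pad tissue. The test takes equal log2 changes of both lists, which start from 7.09 (adipocyte) and 5.79 (epithelial) in 67NR. The adipocyte level was also uneven in 67NR, at 7.69 on array 3 against 6.73 and 6.86 on arrays 1 and 2. The fat markers Pnpla2 and Cfd were at 9.49 ± 0.42 and 9.20 ± 0.47 in 4T07, against 10.03 ± 0.14 and 8.51 ± 0.91 in 67NR. Mammary epithelium without fat was not tested. The mean level of mammary secretory markers was 6.89 ± 0.80 in 4T07 and 5.56 ± 0.41 in 4T1, against 5.15 ± 0.13 in 67NR. A difference between the tumour cells of the lines may account for the rise of the epithelial genes, as a hypothesis.

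Other splits of the 12 arrays into 4 groups of 3, 100 with the real one, were counted. Chance can be excluded for the genes that differ among the lines, where the real split alone, 1 of 100, reached 6312 and the highest other gave 1457. For the genes with an exon-level difference the real split was also alone (1 of 100), but by a narrow margin, 751 against 681. Another grouping gave nearly as many, so how many of the 751 genes reflect the lines cannot be said. For the genes that set a line apart, splits that reached the real count numbered 4 for 67NR (329) and 4 for 168FARN (421), and 6 for 4T07 (76) and 6 for 4T1 (54). This share was under 0.05 for 67NR and 168FARN and above it for 4T07 and 4T1. Each other split was counted by the highest of its 4 groups, whichever group that was. The highest other count was 452. All the other splits that reached the real counts kept 1 line whole, and the highest count without a whole line was 1. The step from 4 to 6 therefore turns on draws that kept a line whole, and does not separate 4T07 and 4T1 from the other lines. Such draws hold part of the real grouping, so the share cannot decide on chance for any of the 4 lines. For the list tests 5 of 100 splits reached 78, with 85 as the highest, so chance cannot be excluded for that number. None of the 4 other splits that reached it kept a line whole, and the other splits had a median of 55. The 6 arrays of a pair allow 10 splits, too few for a share under 0.05. For genes the real counts and highest others were 3710 and 0, 3561 and 0, 3356 and 0 for 168FARN, 4T07 and 4T1 against 67NR, 4248 and 3 and 4688 and 0 for 4T07 and 4T1 against 168FARN, and 357 and 0 for 4T1 against 4T07. For exon probesets they were 820 and 95, 741 and 107, 812 and 82, 840 and 672, 1388 and 111, and 164 and 196, where 2 of the 10 splits reached the real count.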

How the results depend on the processing

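The tests that left out the 2 muscle-high 168FARN arrays or the 2 milk-high 4T07 arrays, and those that required both exon tests, were chosen only after the results were seen. Over all alternatives, 413 counts stayed within 1.5 times and 47 moved further; 1662 list tests kept their call, 206 lost it and 4 turned; and 18684 tests of single genes or probesets kept theirs, 1646 lost it and 3 turned. The number of arrays and the background range of dim probesets limit all counts, and the cause of a moved count was not tested except where fewer arrays, genes or probesets make it.

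With each array left out in turn, the genes differing among the lines ranged from 5401 to 6575, 168FARN against 67NR from 2799 to 4093, 4T07 from 2563 to 3580, 4T1 from 2441 to 3676, 4T07 against 168FARN from 3331 to 4135, 4T1 against 168FARN from 3661 to 5119, and 4T1 against 4T07 from 156 to 531. Genes set apart ranged from 308 to 354 for 67NR, 385 to 522 for 168FARN, 42 to 93 for 4T07 and 31 to 102 for 4T1, and list calls from 72 to 81. Exon counts ranged from 529 to 944 genes among the lines, and from 742 to 956, 631 to 811, 608 to 854, 706 to 1090, 1135 to 1724 and 119 to 439 probesets in the 6 pairs, in the order of the report.

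Without the muscle-high 168FARN arrays there were 1847 genes for 168FARN against 67NR, 2112 for 4T07 and 2470 for 4T1 against 168FARN, 498 genes with an exon difference, and 537 (168FARN against 67NR) and 832 (4T1 against 168FARN) exon probesets. Without the milk-high 4T07 arrays there were 147 genes for 4T1 against 4T07, 38 that set 4T07 apart, 1259 genes with an exon difference and 1415 exon probesets for 4T07 against 168FARN. With an estimated correlation camera called 0 list tests (17 at an unadjusted p under 0.05), and fry called 60. Exon probesets without a probeset filter were 341 for 4T1 against 4T07. With the filter at the 50th percentile they were 484, 421, 501, 490, 754 and 51 in the 6 pairs. Without a minimum change they were 1283 for 168FARN against 67NR and 2557 for 4T1 against 168FARN. In genes that changed less than 2-fold they were 309, 153, 210, 285 and 590 in the first 5 pairs, and 226 genes differed among the lines. The splicing index called 379 (168FARN against 67NR), 533 (4T1 against 67NR), 418 (4T07 against 168FARN), 752 (4T1 against 168FARN) and 9 (4T1 against 4T07), and both tests called 298, 401, 414, 347, 622 and 8.

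Turned values were the B cell list in 4T1 against 4T07 without 4T1 array 2 (0.254, with -0.568 without array 3 as the other end of the range), Nf1 probeset 5339528 in 4T1 against 4T07 without 4T1 array 3 (0.252, with -1.85 without array 2 as the other end), and, without the muscle-high arrays, Myoz1 (-0.00234), Pvalb (-0.249) and the muscle list in 168FARN against 67NR (-0.237) and in 4T07 (0.284) and 4T1 (0.314) against 168FARN.

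The replicate numbers are shared between lines but showed little pairing of the samples: 3 of 18 pairs with the same number correlated above 0.1 (from -0.086 to 0.191, mean 0.036 against -0.018 for other numbers). At exon level an effect shared by number was not excluded, since the block took the genes with an exon difference from 751 to 1059. With the replicate number as a block, 6405 genes differed among the lines, and 3862, 3666, 3457, 4354, 4877 and 349 in the 6 pairs. Under the block 330, 420, 73 and 57 genes set 67NR, 168FARN, 4T07 and 4T1 apart, 76 list tests were called, 1059 genes had an exon difference, and 858, 788, 864, 879, 1440 and 204 exon probesets were called. Each of these counts lay within 1.5 times of its count without the block.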

Other observations

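The tests in this part were set before the results were seen, and none was chosen after. Adipocyte markers gave few calls in any comparison against 67NR: 0 of 16 passed limma's test over all genes in 168FARN and in 4T07 (3 and 1 lower at an unadjusted p under 0.05, and 0 adjusted over the list alone, with camera adjusted p = 0.713 and 0.934, adjusted p = 0.96 and 0.992 with an estimated correlation, and fry adjusted p = 0.966 for each). In 168FARN their median (0.04) and mean (0.01) lay above 0 while camera pointed down. The mammary secretory list in 168FARN had a median of 0.14 and a mean of -0.13, with Csn3 at -2.96 and the estrogen receptor gene Esr1 at 1.06 past the test among 11 genes (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.987, and adjusted p = 0.993 with an estimated correlation). Of the 23 lung metastasis genes in 168FARN, 5 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.981, and adjusted p = 0.992 with an estimated correlation). Their median was -0.26 and their mean 0.27, with the carboxypeptidase inhibitor Lxn at 3.12 and the adhesion gene Vcam1 at 2.80 higher and Ereg at -2.33 lower. Of 31 hypoxia and glycolysis genes in 168FARN, 6 rose and 4 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.962, and adjusted p = 0.992 with an estimated correlation). Their median was -0.01 and their mean 0.02, with Egln3 lower and Car9 (1.45), Bnip3 (1.15) and Car12 (1.06) higher. Of 56 genes with regulated exons, 10 rose and 13 fell in 4T07 against 67NR (12 and 14 adjusted over the list alone; camera adjusted p = 0.896, and adjusted p = 0.992 with an estimated correlation), with a median of -0.12 and a mean of 0.07.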
